A study of Homo sapiens with 6 samples.

How the data were processed

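Poly(A)-selected, strand-marked RNA libraries were made from BoM-1833 breast cancer cells grown with oleic acid, per the labels' protocols. The labels give 2 genotypes, with 3 libraries labelled control and 3 labelled ACBP-knockout. Groups and replicate numbers were taken from the sample titles.

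The deposited counts are whole numbers of reads per Ensembl gene, not normalized, in 1 file per library. Per the submitters' processing notes, the reads were handled with HISAT2 2.1.0, HTSeq 0.11.0 and DESeq2 1.22.2 on GRCh38, with no order or role given. The gene annotation release and the strand setting used for counting are not given in the sources used here, so reads of overlapping and antisense genes may be shared. The last 5 rows of each file are tallies of reads outside single genes. They were kept out of library sizes and tests. Reads assigned to genes made up between 83.3% and 84.2% of the tallied reads. Reads without a unique alignment made up between 7.69% and 8.11%, reads overlapping several genes between 3.59% and 3.71%, reads outside genes between 2.43% and 2.67%, and unaligned reads between 1.84% and 2.39%.

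A deposited table of the authors' own comparison gives, per gene, a log2 fold change with its standard error, and a p-value with an adjusted p-value. Per the file headers, its columns carry the names that DESeq2 writes, and its log2 values are positive where the libraries labelled ACBP-knockout were higher. Another 6 columns of that table hold per-sample values and were not used.

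The count files hold 60664 gene identifiers, of which 60652 were given a symbol from the gene name table or, failing that, from GENCODE 29. Positions, gene types and lengths come from GENCODE 29 on GRCh38, the build named by the submitters. Counts were read into R 4.3.3. Genes were kept with the default settings of filterByExpr in edgeR 4.0.16, which left 15577 genes and 99.9% of all gene counts. Libraries were scaled by the trimmed mean of M-values (TMM), with factors between 0.996 and 1.00. The comparison of 3 against 3 libraries used edgeR's two-sided quasi-likelihood test with group as the single term, and Benjamini-Hochberg adjustment with a threshold of 0.05. Levels are TMM-scaled CPM, that is counts scaled to a common library size, given as mean ± SD. Standard errors of log2 fold changes are the log2 fold change divided by the square root of the F statistic. The common biological coefficient of variation was 3.05%.

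Before the data were examined, 40 gene lists, the designs, the other settings to try and the rule for named genes were fixed. The lists covered lipid metabolism, ferroptosis, stress responses, growth, metastasis, signalling, RNA quality, genes beside DBI, and markers of other cell types. Of 955 list members, 954 were matched to an identifier. Lists with at least 5 tested members, 37 in all, were tested with camera in limma 3.58.1, which compares the genes of a list with all other genes. It ran on log2 CPM with a prior count of 2 and its preset correlation of 0.01, adjusted over the lists. For each list, members past the threshold were counted over all genes tested and adjusted over the list alone.

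The text names DBI, related acyl-CoA-binding genes and a fixed set of lipid, ferroptosis and bone metastasis genes whatever their values. It also names the 10 genes that rose and the 10 that fell most among genes with a mean log2 CPM of at least 2, a symbol and no overlap between groups, and up to 4 members of each list with the smallest p. Some genes that meet this rule are not reported here. Genes named outside this rule are said to be chosen after their values were seen.

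The tests were run first on simulated counts drawn from the means and library sizes of these libraries. Of 50 genes changed at each size, edgeR recovered 14% at 1.1-fold, 66% at 1.25-fold, 74% at 1.5-fold and 96% at 2-fold. It called 0.052% of unchanged genes among 15406 tested. In the real comparison 43% of genes were called, and the Benjamini-Hochberg threshold is stricter where few genes change. These shares therefore do not carry over directly to it. camera called 10 of 10 shifted lists of 25 genes and 0 of the unshifted ones. The simulated genes were drawn independently of each other, so this could not show how camera treats lists of correlated genes.

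Other settings fixed in advance were DESeq2's size factors, upper quartile scaling, no count filter, a filter of 1 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, limma-voom, a replicate block, each library left out in turn, a test against a 1.5-fold change, an adjusted p under 0.01, camera with estimated correlations, fry, a prior count of 0.5, and a 2-fold limit on the authors' calls. After the data were examined, an alternative was added that removes, for each gene, the median log2 fold change of the other tested genes within 5 Mb. That median used genes with a mean log2 CPM of at least 3 and needed at least 10 of them. It was removed as a fixed value, so p-values of that alternative leave out the spread of the neighbours around it.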

Results

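RNA was sequenced from BoM-1833 cells, a bone-tropic derivative of the human breast cancer line MDA-MB-231, grown with the monounsaturated fatty acid oleic acid. The comparison asks which genes and pathways follow the loss of ACBP, the acyl-CoA-binding protein, which is encoded by DBI and binds long-chain acyl-CoA esters. The labels give 3 control libraries and 3 libraries labelled ACBP-knockout. Gene counts summed to 25624689, 29739154 and 22124655 in control replicates 1, 2 and 3, and to 23367273, 24006242 and 34005553 in replicates 1, 2 and 3 labelled ACBP-knockout. Unaligned reads made up 2.31% ± 0.10 of the tallied reads (SD, n = 3) in the controls and 1.90% ± 0.054 (SD, n = 3) in the libraries labelled ACBP-knockout. At these depths 3 counts correspond to between 0.0882 and 0.136 CPM (counts scaled to a common library size), a floor that covers counting error only. Replicates of a group differed by more than counting noise, with a chi-squared per degree of freedom between 1.41 and 3.93. It was 3.10 and 2.48 in pairs with control replicate 1, and 1.41 between control replicates 2 and 3. In pairs with ACBP-knockout replicate 2 it was 3.30 and 3.93, and 1.47 between ACBP-knockout replicates 1 and 3. No label says that the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

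DBI, the targeted gene, was higher in the libraries labelled ACBP-knockout, so its RNA level does not bear out the labels. DBI (ENSG00000155368) is a protein-coding gene on the plus strand of chromosome 2, from 119366921 to 119372560 (GRCh38). Its counts were 1124, 1253 and 908 in control replicates 1 to 3 and 2302, 2486 and 3381 in the libraries labelled ACBP-knockout. The level was 42.4 ± 1.54 CPM (SD, n = 3) in the controls and 100.5 ± 2.51 CPM (SD, n = 3) in the libraries labelled ACBP-knockout. This is a 2.37-fold difference (log2 fold change 1.24 ± 0.042 SE, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.56e-17). The authors' deposited table has DBI in the same direction (that table's own adjusted p = 6.42e-78). Gene counts show neither the edit nor the protein, so this level does not show that the labels are wrong either. Every direction below is drawn between groups whose labels DBI does not bear out.

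**Figure D1:**
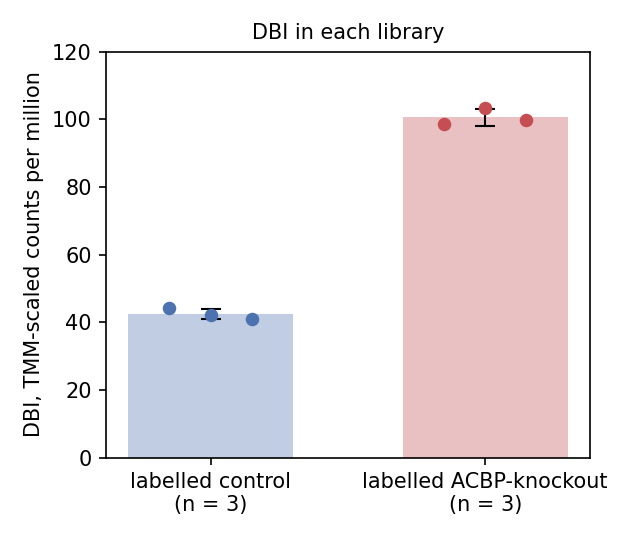
DBI in TMM-scaled CPM (vertical axis) in the libraries labelled control and ACBP-knockout. Points are libraries, bars are means and error bars are SDs (n = 3); the libraries labelled ACBP-knockout sit at 98.5, 103.3 and 99.8, all above the controls at 44.1, 42.1 and 41.1.

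Of 12 tested genes beside DBI, 3 rose, 2 fell and 7 did not pass (3 rose and 1 fell adjusted over the list alone). Those with the smallest p were INHBB, which encodes an activin subunit and rose 3.46-fold, and EPB41L5, which rose 1.30-fold. The list as a group did not pass (camera, Benjamini-Hochberg adjusted p = 0.763).

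In the libraries labelled ACBP-knockout, whose DBI level does not bear out the label, 3397 genes rose and 3300 fell of 15577 tested. Most changes were small. The median size of the log2 fold change of changed genes was 0.29, and 80.6% of them lay under 1.5-fold. At least 2-fold changes numbered 269 up and 245 down. The groups did not overlap at 50.9% of genes, where chance gives 10%. The first principal component held 67% of the variance and separated the groups.

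The largest rises by the fixed rule were those of CD96, an immunoglobulin-family receptor (10.5-fold), MXRA8 (6.61-fold), the dystrophin gene DMD (6.51-fold) and GALNT5, a glycosyltransferase gene (6.17-fold). LINC01582 (5.32-fold), the tight-junction gene CLDN4 (5.28-fold), the cytochrome P450 gene CYP2S1 (5.26-fold), NLRP2 (4.56-fold) and the monocyte chemokine gene CCL2 (4.40-fold) followed. The largest falls were those of IGFN1 (17.1-fold lower), the osteoclast-associated receptor gene OSCAR (11.6-fold lower), MSMP (6.35-fold lower) and ITM2A (5.59-fold lower). IL13RA2, a decoy receptor of interleukin 13, was 5.34-fold lower and the gelatinase gene MMP9 was 5.27-fold lower. DHRS2 (4.42-fold lower), ESM1 (4.33-fold lower), CACNA2D4 (3.83-fold lower) and UBBP4 (3.74-fold lower) completed the list. UBBP4 is a ubiquitin pseudogene whose reads can be shared with other ubiquitin genes, so its value is uncertain. IL13RA2 fell from 149.8 ± 2.43 to 28.1 ± 1.08 CPM (SD, n = 3 each), and CD96 rose from 0.798 ± 0.149 to 8.48 ± 0.969 CPM. Genes within 5 Mb had a median log2 fold change of -0.34 around IGFN1 and 0.27 around MSMP, small beside the changes of these genes.

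Inflammatory genes fell together in the libraries labelled ACBP-knockout, again with the direction set by labels that DBI does not bear out. Of 25 tested NF-kappaB and inflammatory targets, 20 fell, 2 rose and 3 did not pass (20 fell and 2 rose adjusted over the list alone). The median log2 fold change was -0.41 (camera, Benjamini-Hochberg adjusted p = 6.27e-07; adjusted p = 0.121 with an estimated correlation). IL1B, which encodes interleukin 1 beta, fell from 915.9 ± 14.3 to 297.7 ± 6.14 CPM (SD, n = 3 each; log2 fold change -1.62 ± 0.032 SE, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.91e-22). IL1A fell 2.59-fold and the cyclooxygenase gene PTGS2 fell 2.06-fold. The genes within 5 Mb of PTGS2 had a median log2 fold change of -0.29, and PTGS2 was at -0.75 once that was removed. The members that rose were CCL2 and TRAF1, the latter 1.28-fold and chosen after its value was seen.

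The list of MDA-MB-231 bone metastasis genes, 20 names fixed in advance and not a full published signature, moved up. Of its 17 tested members 11 rose, 3 fell and 3 did not pass, over all genes and adjusted over the list alone (median log2 fold change 0.26, camera, Benjamini-Hochberg adjusted p = 0.0072; adjusted p = 0.308 with an estimated correlation). The protease gene ADAMTS1 rose 1.96-fold, the matricellular gene CCN2 rose 1.51-fold and the proteoglycan gene SRGN rose 1.37-fold. The chemokine receptor gene CXCR4 rose 2.18-fold from 1.83 ± 0.527 CPM (SD, n = 3). IL11 and the collagenase gene MMP1 rose by 0.26 and 0.14 on the log2 scale. The members that fell, named after their values were seen, were PHLDB2 (-0.32), MCAM (-0.19) and TNFRSF11B (-0.60), the last encoding osteoprotegerin, an inhibitor of osteoclast formation. In the list of osteolytic and osteomimicry factors, 6 of 18 rose, 5 fell and 7 did not pass, the same counts adjusted over the list alone, and the list did not pass (camera, Benjamini-Hochberg adjusted p = 0.999). Its 4 members with the smallest p were IL1B (3.08-fold lower), CCL2 (4.40-fold higher), MMP9 (5.27-fold lower) and CSF1, which encodes a macrophage growth factor and rose 1.48-fold among genes with a median of 0.32. PTHLH had a log2 fold change of 0.15 and RUNX2 of 0.013, and neither passed. RUNX2 lies among genes with a median log2 fold change of 0.57, and it was at -0.56 with that median removed. That fit called RUNX2 but took the median as free of error. The log2 fold changes of genes from 40 to 60 Mb of chromosome 6 had an SD of 0.268, so the call does not show a fall of RUNX2.

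Cell-cycle genes of G2 and M phase rose slightly. Of 27 tested, 19 rose, 0 fell and 8 did not pass, over all genes and adjusted over the list alone (median log2 fold change 0.16, camera, Benjamini-Hochberg adjusted p = 0.000676; adjusted p = 0.691 with an estimated correlation). ECT2 rose 1.27-fold, CDC20 1.24-fold and KIF11 1.21-fold, and TOP2A rose by 0.28 on the log2 scale. The S phase list did not pass, with 6 of 28 up, 4 down and 18 not passed, the same counts up and down adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.625). RRM2 rose 1.37-fold and MCM3 1.31-fold, and the medians around them were 0.35 and 0.37 on the log2 scale. Removing that shift left MCM3 at 0.017 and not past the threshold. All 9 tested replication-dependent histone genes rose, also adjusted over the list alone (median log2 fold change 0.84, camera, Benjamini-Hochberg adjusted p = 0.000251; adjusted p = 0.211 with an estimated correlation). H1-2 rose 2.47-fold, H4C8 1.87-fold, H2AC6 1.79-fold and H2BC5 1.48-fold. Histone genes share near-identical copies, so the level of each is uncertain.

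Mitochondrially encoded genes fell. Of 13 tested, 12 fell and 1 did not pass, over all genes and adjusted over the list alone (median log2 fold change -0.28, camera, Benjamini-Hochberg adjusted p = 0.000251; adjusted p = 0.684 with an estimated correlation). MT-CO2 fell 1.32-fold, MT-ND4L 1.32-fold, MT-CO3 1.29-fold and MT-CYB 1.27-fold. The member that did not pass, MT-ND3, named after its value was seen, had a log2 fold change of -0.10, and it passed at -0.21 without control replicate 2 and was at 0.029, not past the threshold, without control replicate 1. Their share of gene counts was 1.54% ± 0.075 (SD, n = 3) in the controls and 1.24% ± 0.060 (SD, n = 3) in the libraries labelled ACBP-knockout. Of 41 genes of cytosolic ribosomal proteins 23 fell, 5 rose and 13 did not pass, against 25 and 5 adjusted over the list alone (median log2 fold change -0.11, camera, Benjamini-Hochberg adjusted p = 0.0016; adjusted p = 0.792 with an estimated correlation). These genes have many processed pseudogenes that can share reads, so single levels are uncertain. RPS27 fell 1.49-fold, RPL7A 1.46-fold and RPL30 1.32-fold, while RPS6 rose 1.27-fold. Genes within 5 Mb had a median of -0.41 around RPS27 and -0.33 around RPL7A.

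**Figure D2:**
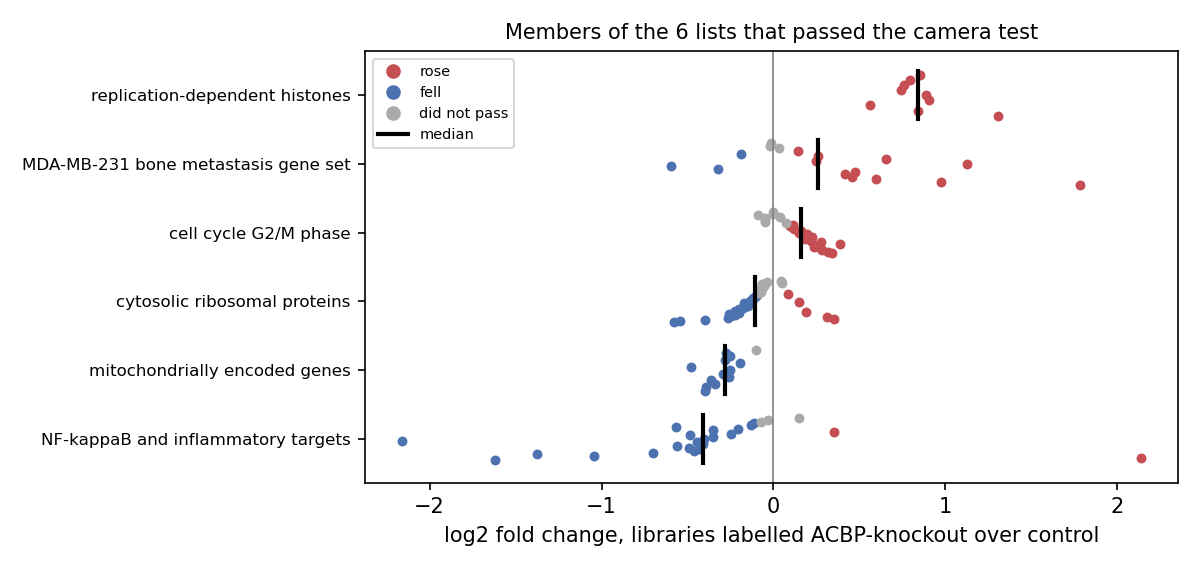
Log2 fold change (horizontal axis, libraries labelled ACBP-knockout over control) of each tested member of the 6 lists that passed the camera test. Points are genes, coloured by whether they rose, fell or did not pass, and black bars are list medians, from 0.84 for histone genes to -0.41 for NF-kappaB and inflammatory targets.

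Lipid genes changed individually, and no lipid list passed. The lipid droplet coat gene PLIN2 rose from 232.8 ± 13.7 to 428.7 ± 20.8 CPM (SD, n = 3 each; 1.84-fold). G0S2, which encodes an inhibitor of triglyceride lipase, fell 2.18-fold. Genes within 5 Mb had a median log2 fold change of 0.36 around PLIN2 and -0.30 around G0S2, and with it removed these genes were at 0.52 and -0.82. AGPAT3 rose 1.57-fold and LPIN1 by 0.59 on the log2 scale, among genes with medians of 0.33 and 0.35. In the lipid droplet and triglyceride list 8 of 22 rose, 7 fell and 7 did not pass, against 8 and 8 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.763).

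Of 30 genes of fatty acid oxidation 5 rose, 7 fell and 18 did not pass, with the same 5 and 7 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.86). CPT1A, whose product admits long-chain fatty acids to mitochondria, rose 1.36-fold, ECI2 rose 1.26-fold and ETFA fell 1.21-fold. ECHS1 fell 1.35-fold among genes with a median of -0.45, and its log2 fold change was 0.014 once that was removed. CPT2 (log2 fold change 0.004), HADHA (-0.021), ACADVL (0.073) and PPARGC1A (0.15) did not pass. ACADVL passed at 0.095 without ACBP-knockout replicate 2. It was also called at 0.091 with the median of its neighbours removed, in a fit that left out their spread. CPT2 sits among genes with a median of 0.32, and it was at -0.31 with that median removed. The same fit called CPT2, but for that reason the call does not show a fall of CPT2. Among 13 PPAR targets 5 rose, 2 fell and 6 did not pass, unchanged when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.175). ACSL3 rose 1.33-fold and PDK4 1.39-fold, while ANGPTL4, a lipoprotein lipase inhibitor gene, fell 1.64-fold.

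Of the other acyl-CoA-binding genes ACBD6 fell 1.42-fold and ACBD3 fell by 0.27 on the log2 scale, both on the long arm of chromosome 1 among genes with medians of -0.32 and -0.22. ACBD3 did not pass once its surroundings were removed (log2 fold change -0.045). ACBD5 (-0.007) and ACBD7 (0.057) did not pass. In the list of acyl-CoA binding, activation and thioesterase genes 8 of 26 rose, 3 fell and 15 did not pass, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.868). With the shift of neighbouring genes removed, 7 of them rose and 6 fell. SCP2 rose 1.35-fold among genes with a median of 0.31. TSPO, the mitochondrial partner that binds the DBI product, fell by 0.27 on the log2 scale. In the list of mitochondrial steroid genes and TSPO partners 3 of 13 rose, 4 fell and 6 did not pass, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.792).

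Cholesterol synthesis and uptake genes gave 11 up, 5 down and 9 not passed of 25, or 12 and 5 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.418). LSS, the lanosterol synthase gene, rose 1.41-fold and PMVK, a kinase gene of the mevalonate pathway, fell 1.47-fold. These genes lie among genes with medians of 0.36 and -0.42. HMGCS1 (log2 fold change 0.11) did not pass with all libraries and passed at 0.15 without control replicate 2 and at 0.14 without ACBP-knockout replicate 1. In fatty acid synthesis and desaturation 9 of 21 rose, 2 fell and 10 did not pass, or 9 and 3 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.308). SCD5 rose 1.39-fold, ELOVL6 1.27-fold and FADS2 1.26-fold, SREBF1 fell 1.31-fold, and SCD (0.072) and FASN (-0.028) did not pass. Of 22 sphingolipid synthesis genes 7 rose, 4 fell and 11 did not pass, or 8 and 4 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.625).

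Ferroptosis genes went both ways. Of 24 suppressing genes 6 rose, 6 fell and 12 did not pass, and of 18 promoting genes and markers 2 rose, 6 fell and 10 did not pass, with the same counts adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.625 and 0.284). SLC7A11, the cystine transporter gene, rose 1.51-fold and its partner SLC3A2 rose 1.15-fold, while the ferritin genes FTH1 and FTL, whose reads can be shared with processed pseudogenes, fell 1.29-fold and 1.19-fold. GPX4, whose product reduces lipid peroxides, fell by 0.14 on the log2 scale, and ACSL4 rose from 84.0 ± 2.68 to 101.0 ± 4.97 CPM (SD, n = 3 each). CARS1 fell 1.15-fold and CYB5R1 fell 1.29-fold, the latter among genes with a median of -0.34. With the median of their neighbours removed, GPX4 (-0.075) and CYB5R1 (-0.025) did not pass. HMOX1 (-0.12) and CHAC1 (0.090) did not pass. HMOX1 passed at -0.20 without ACBP-knockout replicate 3, and CHAC1 at 0.16 without ACBP-knockout replicate 2.

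No stress or energy list passed. Counts up, down and not passed were 5, 9 and 8 for NRF2 targets (camera, Benjamini-Hochberg adjusted p = 0.625), 6, 10 and 11 for the integrated stress response (adjusted p = 0.678), 5, 8 and 10 for the unfolded protein response (adjusted p = 0.763) and 5, 7 and 11 for heat shock and immediate early genes (adjusted p = 0.868). These counts were the same adjusted over the list alone, and the heat shock and immediate early genes with the smallest p, IER2 and JUNB, fell 1.41-fold and 1.43-fold. Nuclear genes of oxidative phosphorylation gave 4 up, 13 down and 29 not passed, or 4 and 12 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.284). SDHC fell 1.38-fold among genes with a median of -0.44, and it did not pass with that median removed (-0.028). The tricarboxylic acid cycle gave 8, 5 and 16, or 8 and 6 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.763), and its member with the smallest p, IDH2, was 1.75-fold lower among genes with a median of -0.25. Glycolysis gave 9, 6 and 8, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.763), and its member with the smallest p, ALDOC, was 2.33-fold higher. With the shift of neighbouring genes removed, 5 glycolysis genes rose and 7 fell. PFKL rose among genes with a median of 0.35 and did not pass with it removed (0.067). Hypoxia targets gave 8, 9 and 8, or 9 and 9 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.99). Autophagy and lysosome genes gave 7, 6 and 16, or 8 and 6 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.75), and those with the smallest p, CTSD and MITF, were 1.68-fold and 1.67-fold higher.

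Among signalling lists, TGF-beta/SMAD targets gave 5 up, 12 down and 4 not passed of 21, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0983). LTBP3 fell 2.18-fold, LTBP2 1.83-fold and TGFBI 1.75-fold. With the shift of neighbouring genes removed, an alternative chosen after the data were examined, this list passed (camera, adjusted p = 0.0196) but did not pass there with an estimated correlation (adjusted p = 0.316 with an estimated correlation). Without that removal, camera gave adjusted p from 0.0866 to 0.576 for it, and the list did not pass in any camera setting tried. It passed in fry (adjusted p = 0.000342 in the directional test and 3.66e-07 in the mixed test), which does not compare a list with other genes. Type I interferon genes gave 10 up, 4 down and 11 not passed, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.258). With the shift of neighbouring genes removed, 9 of them rose and 8 fell. BST2, the tetherin gene, rose 3.25-fold, OAS1 2.53-fold, OAS2 1.91-fold and IFITM1 1.60-fold. YAP/TAZ targets gave 7, 10 and 5, or 7 and 11 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.625). MYC targets gave 3, 6 and 18, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.625). p53 targets gave 8, 7 and 10, or 8 and 9 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.925), and CDKN1A (log2 fold change -0.078) did not pass. CDKN1A passed with genes limited to 1 CPM in 3 libraries (-0.080). It was also called with the median of its neighbours removed (-0.19), in a fit that left out their spread. Epithelial-mesenchymal transition genes gave 6, 9 and 6, or 6 and 10 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.678). FN1 fell 1.40-fold and S100A4 rose 1.81-fold among genes with a median of -0.41. Median, mean and test differed in sign for 5 of the lists that did not pass. Glycolysis had a median of -0.001 and a mean of 0.061 with the test up, and the acyl-CoA list -0.011 and -0.004 with the test up. With the test down, heat shock genes had 0.021 and -0.037, p53 targets 0.001 and 0.007, and epithelial-mesenchymal genes -0.030 and 0.061.

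Markers of other cell types went in both directions. Luminal epithelial genes gave 4 up, 2 down and 6 not passed (camera, Benjamini-Hochberg adjusted p = 0.284), basal genes 2, 2 and 2 (adjusted p = 0.999) and endothelial genes 1, 4 and 1 (adjusted p = 0.214), each also adjusted over the list alone. SPDEF rose 2.70-fold, KRT19 rose 1.67-fold and KRT18 fell 1.13-fold. KRT17 rose 2.99-fold from 0.403 ± 0.031 CPM (SD, n = 3), and LAMB3 fell 1.38-fold among genes with a median of -0.31. ROBO4 fell 1.41-fold, TIE1 1.80-fold and EGFL7 1.57-fold, the last among genes with a median of -0.36, and ESAM rose 1.38-fold. Of 3 tested fibroblast genes 2 rose and 1 fell, of 4 blood genes 1 rose and 1 fell, and of 4 embryonic kidney genes 1 rose and 1 fell, also adjusted over each list alone; these lists were too short to test. PDGFRB rose 1.68-fold and COL1A1 fell 1.23-fold, LCP1 rose 1.56-fold and CD14 fell 2.24-fold, and SIX2 rose by 0.32 on the log2 scale and PAX8 fell 1.18-fold. COL1A1 missed the threshold without control replicate 3 (log2 fold change -0.23) and PAX8 without ACBP-knockout replicate 1 (-0.20) and in DESeq2 (-0.23).

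Genes that lie near each other on a chromosome shifted together, a feature examined only after the data were seen. Windows and segments used genes with a mean log2 CPM of at least 3. The medians of 278 windows of 10 Mb had an SD of 0.142 in log2 fold change, against at most 0.0492 in 1000 shuffles of gene positions. In 41 windows the median passed 0.2 in size, 23 higher and 18 lower in the libraries labelled ACBP-knockout. In each of these the groups did not overlap, which picking windows by their group difference makes likely. Window medians of single libraries against their group had SDs from 0.017 to 0.046. On chromosome 1, from 20 to 120 Mb, 367 of 457 genes rose and 12 fell (median 0.27 ± 0.217 SD across genes). From 150 to 250 Mb of the same chromosome, 368 of 435 fell and 12 rose (median -0.31 ± 0.332 SD). On chromosome 6, from 40 to 60 Mb, 65 of 72 genes rose (median 0.54). Around DBI, from 110 to 130 Mb of chromosome 2, the median of 46 genes was -0.033. Segment bounds were chosen after the windows were seen, and 71.3% of genes whose neighbours passed 0.2 were called, against 36.4% where neighbours lay under 0.1.

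**Figure D3:**
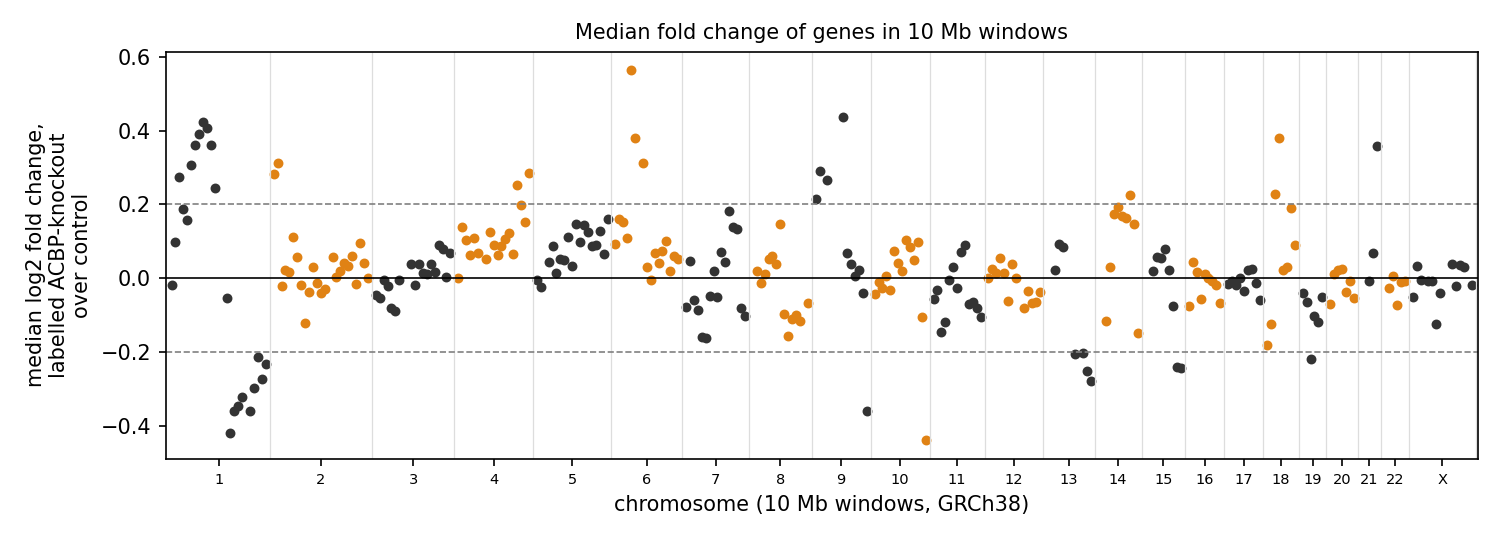
Median log2 fold change (vertical axis, libraries labelled ACBP-knockout over control) of the genes in each 10 Mb window along the chromosomes (horizontal axis, GRCh38), with alternating colours for neighbouring chromosomes and dashed lines at 0.2 and -0.2. Each point is 1 window, and 41 of 278 lie past the dashed lines, with opposite signs on the 2 sides of chromosome 1.

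The authors' deposited table calls 3833 genes at its adjusted p under 0.05, 1994 higher and 1839 lower. Of its calls 3830 were also called here with the same sign, and 2867 genes were called here alone. It gives -1.63 for IL1B, 2.15 for CCL2 and -2.41 for MMP9 as log2 fold changes. Across the genes tested here, which are not independent replicates, the log2 fold changes had a correlation of 0.987. That table appears to leave out control replicate 3. It gives -2.063 for UBBP4, against -1.904 here, with control replicates 1 to 3 at 13.45, 12.99 and 8.684 CPM. For CPT1A it gives 0.494, against 0.442 here, with these controls at 132.6, 132 and 147.3 CPM. For CXCR4 it gives 0.938, against 1.127 here, with these controls at 2.118, 2.149 and 1.221 CPM. For LTBP2 it gives -0.809, against -0.873 here, with these controls at 47.77, 51.43 and 56.58 CPM. Its DBI value is 1.224, against 1.244 here with all libraries and 1.224 without control replicate 3. Without ACBP-knockout replicate 2 DBI was at 1.226, so DBI alone does not decide. Each difference goes the way that leaving out control replicate 3 gives. UBBP4, CPT1A, CXCR4 and LTBP2 were chosen after their values were seen. The shared calls, the 2867 genes and the correlation thus appear to compare different sets of libraries. That was not tested over all genes.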

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

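The neighbourhood alternative was chosen after the data were examined; all others were planned. The count of changed genes stayed within 1.5 times of 6697 under other scalings, filters, DESeq2 (5189), limma-voom and an adjusted p under 0.01 (5091), and ran from 5790 to 6501 without 1 library, rose from 2931 to 3351 and fell from 2821 to 3150. A test against a 1.5-fold change left 522 genes, 294 up and 228 down, since it asks for larger changes. The replicate numbers did not pair the samples (correlations of same-numbered deviations -0.053, -0.012 and 0.043), and the replicate block called 6560 genes. DBI stayed higher and past the threshold in each alternative that refitted the counts gene by gene, by at most 1.27 on the log2 scale. Of 37 lists tested, 6 passed in camera with its preset correlation and 0 with an estimated correlation (3 at an unadjusted p under 0.05). In fry, 25 of 37 passed its directional and 37 its mixed test, which do not compare a list with other genes; the cause of the loss in camera was not tested. The authors' 3833 calls become 374 at 2-fold. Over the other planned settings of 137 named genes, 1769 of 1781 values stayed on their side of the threshold, 6 of these with a changed sign in genes not past it. Of the others 9 newly passed and 3 no longer did, and 0 called values reversed. With the neighbourhood shift removed 5339 genes were called and 7 lists passed in camera with its preset correlation, and none with an estimated one (lowest adjusted p = 0.082); 4267 of the calls were kept with their sign, and 130 reversed. Among named genes CPT2 became -0.31, RUNX2 -0.56 and ECHS1 0.014, because the median of their neighbours was subtracted. The spread of neighbours around that median did not enter the calls of this alternative. Small changes can be missed. In simulated data at these depths, with 3 libraries per group, 14% of 1.1-fold changes were recovered. The part of depth in this was not tested. Far fewer genes were changed there than were called here, which makes the adjusted threshold stricter, so that share does not carry over directly.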

Other observations

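The 4 lists of the next sentences were written after the data were examined and hold genes whose values had been seen, so only the edgeR counts of their members are given and no test of a list. Of 15 tested carriers of amino acids, 10 rose in the libraries labelled ACBP-knockout, 1 fell and 4 did not pass, also adjusted over the list alone. SLC38A4 rose from 2.00 ± 0.281 to 6.52 ± 0.242 CPM (SD, n = 3 each), and SLC7A2 from 38.6 ± 0.965 to 58.1 ± 1.80 CPM. Of 14 genes of MHC class I and antigen presentation 6 rose, 1 fell and 7 did not pass, or 7 and 1 adjusted over the list alone. B2M rose from 329 ± 6.03 to 493 ± 10.5 CPM (SD, n = 3 each). The HLA genes share reads with each other and sit among genes with a median log2 fold change of about 0.11. The published MDA-MB-231 lung metastasis signature gave 5 up, 10 down and 2 not passed of 17, also adjusted over the list alone. Its members LTBP1 and IL13RA2 went opposite ways, 2.44-fold up and 5.34-fold down. Cancer-testis antigens and related genes gave 2 up, 6 down and 2 not passed of 10, also adjusted over the list alone. MAGEB2 was 2.86-fold lower and the related gene TSPYL5 was 2.55-fold lower. The members that rose were SSX1, by 0.59 on the log2 scale, and MAGEA12, which went from 0.0938 ± 0.0367 CPM (SD, n = 3), near the floor of 3 counts, to 1.01 ± 0.167 CPM (SD, n = 3). Members of these 4 lists were named after their values were seen.

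In the 3 patterns weighed next, the tests of copy number, of gene order, of the genes around DBI, of exchanged labels, of S phase and of the genes around histone genes were written after the result was seen. Runs of neighbouring genes shifted together between the groups. The SD of window medians, 0.142, lay above the highest of 1000 shuffles, 0.0492, which argues against chance order, and it kept 0.958 of its size after a trend on GC content was removed. A candidate explanation is a copy-number difference between the cells of the groups, such as between clones grown out after editing. Genes lay on the side of their neighbours in 72.1%, 91.7% and 95.1% of cases from the lowest to the highest of 3 classes of expression. Copy number had been taken to need over 75% in each, so the lowest class missed that bound. That class holds the genes with the fewest counts, where counting noise alone lowers this share, so the miss cannot decide against copy number. RNA alone leaves a DNA difference and regional regulation open, so these cannot be told apart, and a difference by genotype stays untested.

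DBI was higher in the libraries labelled ACBP-knockout, by 58.1 CPM on average. The median log2 fold change of genes within 5 Mb was 0.019, so a shift of the region does not account for it. Annotated DBI pseudogenes summed to 0.878 ± 0.0897 CPM (SD, n = 3) in the controls, so the reads counted there were too few to have supplied the gain. Reads without a unique alignment were tallied apart and counted at no gene. Whether control reads of DBI went to that tally was not tested. Whether the labels of the groups were exchanged cannot be told apart from a rise of the edited gene's transcript: the lowest library labelled ACBP-knockout was 54.4 CPM above the highest control, which both would give.

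The 9 tested replication-dependent histone genes rose, with a median log2 fold change of 0.84. With the shift of their neighbours removed the median was 0.71, so position alone does not explain it. The S phase list had a median of 0.031 (95% bootstrap interval over its genes -0.011 to 0.054), so it did not rise along with the histone genes. That interval resamples genes that are not independent and holds no spread between libraries. It therefore cannot decide whether more cells were in S phase. Carry-over of RNA without poly(A) tails stays open, since only 4 small RNA genes were tested, with a median of 0.013 and a 95% bootstrap interval from -0.135 to 0.464. A genotype effect on these genes was not tested apart from the group labels.

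The real grouping gave 6697 changed genes and 6 lists. The highest of the other splits of the 6 libraries into 3 and 3 gave 0 genes and 4 lists in the same edgeR and camera tests. Each of the other splits has libraries of both groups on either side. The group difference then adds to the spread within a side, so the 0 genes there say little about chance. Most of the other splits called at least 1 list with 0 genes. Thus camera with its preset correlation can call a list where no gene passes. The real split was the 1 of 10 that gave as many genes, and the 1 of 10 that gave as many lists. With 10 splits no share under 0.05 can be reached.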
